A study of Zea mays with 8 samples.

How the data were processed

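Total RNA of maize seedlings was measured on 1-colour Agilent arrays (Cy3). The 8 samples were 4 pools of plants inoculated with rice black streaked dwarf virus (RBSDV) and 4 mock-inoculated pools, each of 10 seedlings of the genotype Zheng 58. Groups and replicate numbers were taken from the labels. Per the labels' protocols, seedlings 15 days old were exposed to 5 planthoppers each for 3 days, grown at 25 °C until white streaks appeared, and their aerial parts were harvested. Per the labels, 2 µg of total RNA was labelled for each array, and the replicates were inoculated and harvested independently. The labels do not say that a replicate number marks a shared set of infected and mock plants.

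Each array's deposited scanner table gives the intensity of every spot, background-subtracted and detrended by Feature Extraction 10.7.3.1 per the file headers. The submitters' processing notes name Agilent Feature Extraction 9.5. No normalization between arrays had been applied to these intensities. The deposited value table holds log2 values. Its scale and centring were not given in the sources used here and were found by setting each column against the scanner signal. The slopes on log2 signal lay between 0.959 and 1.14, and every column shared a minimum of 1.09 and a maximum of 19.2, with medians of 7.28, as after quantile normalization. The columns named for mock replicates 3 and 4 held each other's scanner values (Spearman correlation across probes 1 with the other array and 0.945 with their own). Which of the pair of labels is right stays unknown. It moves no sample between groups, and the numbers of the scanner tables were used.

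The 42034 gene probes carry 39174 sequence IDs, of which 36669 have 1 probe. Control spots were left out, and so were 1 to 7 spots per array marked as outliers. No gene spot was saturated. The intensity was converted to log2 and each array's 75th percentile was subtracted. A probe was tested if it was well above background on at least 3 of the 4 arrays of either group, which left 35984 probes and removed 6050. Differences between RBSDV and mock were tested with limma 3.58.1 (lmFit and eBayes, in R 4.3.3) on all 8 arrays without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. The groups, this test, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

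The array barcodes in the file headers place the 8 arrays on 2 slides. Slide 1 holds RBSDV replicates 1 and 3 and mock replicates 1 and 4, and slide 2 holds RBSDV replicates 2 and 4 and mock replicates 2 and 3. Slide was tested as a block, as a term that may change the difference, and by fits within each slide. The block assumes that slides shift both groups alike. Spot noise was estimated from 7 bright control probes (E1A) with 32 spots each, and compared with the robust SD of the difference between arrays over 14323 bright probes. The controls lay 3.44 to 4.25 above the 75th percentile on the log2 scale. They were brighter than many of the probes compared, which had a mean log2 signal over 9. Ratios to this spot noise are therefore approximate. Because the mock arrays of a slide differed by about that noise, the mean ± SD of the mock group treats each such pair as 1 sample (n = 2). A second limma fit with the mock pairs averaged is given beside the planned one. It was added after the data were seen.

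The files pair almost no ID with a gene. The reference gene table (assembly Zm-B73-REFERENCE-NAM-5.0) matched 2 of the 39174 IDs, with 4 probes, and none of the 41 gene lists fixed for this tissue and virus, markers of cell types and of other tissues included, reached 3 matched probes (0 lists). No gene list was therefore tested. The rule for named genes took the 12 highest and the 12 lowest differences past the threshold, with the 4 RBSDV values all on one side of the 4 mock values and an informative gene name. No such probe had a name, so the rule's ranking is given for 2 IDs in each direction, by ID only. In addition, 22 probes whose ID is a gene name, or that matched a locus, are described, 20 of them tested. They were chosen after the files were seen, because they carry names. The serial numbers before the names of the Mutator probes are left out. Their sets were tested with limma's camera (preset inter-gene correlation) and fry, adjusted over the 2 sets with several tested probes.

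The tests were checked on simulated data with the measured spread of the 35984 probes. With 8 independent arrays and 50 probes changed at each size, 7 were recovered at a log2 fold of 1, 32 at 2, 42 at 3 and 44 at 5, with 8 false calls. Arrays of a slide and group then shared their deviations, with spreads within and between pairs pooled over both groups. The data differed from this: the SD of the slide difference over probes was 1.2 in mock and 0.623 in RBSDV. With nothing changed, the fit to 8 arrays called a median of 1322 probes over 20 draws (1192 to 1410). The fit with mock pairs averaged called a median of 17 (0 to 51). With probes changed in the same structure, the latter recovered 4, 23, 39 and 40 of 50 at those sizes and made 144 false calls.

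Alternatives were normexp background correction (offset 50, on median signals because mean signals are not among the columns used here), quantile normalization, median scaling, other filters on dim probes, the deposited value table, another model of the spread, array weights, blocks for replicate number and slide, leaving out each array, and an adjusted p under 0.01. The number of arrays limits the precision. The percentage of probes well above background on each array, from 81.4 to 95.5, is the measure of depth. A probe not well above background on any array of a group has only a bound there. Its fold is given as at least the bright group's mean over the dim group's, with each dim array at the higher of its own value and the lowest signal well above background on that array.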

Results

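Rice black streaked dwarf virus (RBSDV) is a planthopper-borne fijivirus that stunts maize and streaks its leaves. Its effect on gene expression was measured in the aerial parts of Zheng 58 maize seedlings, with 4 RBSDV-inoculated pools and 4 mock-inoculated pools of 10 plants each. Of the 42034 gene probes, 81.9 to 84.5% were well above background on the RBSDV arrays and 81.4 to 95.5% on the mock arrays. The 75th percentile of the signal was 1170 to 1350 on the RBSDV arrays and 758 to 1122 on the mock arrays. The net signal of the negative controls was 29.9 and 17.4 on mock replicates 2 and 3 and 12.8 to 14.7 on the other arrays.

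Many probes differed between the infected and the mock-inoculated samples in the fit to 8 arrays, but mock arrays also differed widely between slides. Over bright probes the robust SD was 0.84 to 0.87 between mock arrays of different slides and 0.52 to 0.87 between RBSDV and mock arrays. After percentile scaling more of the called probes were lower than higher in RBSDV. The balance turned to 1668 higher and 1499 lower after quantile normalization, and to 4670 higher and 811 lower after scaling to control probes. In the limma fit to 8 arrays, 1040 of 35984 tested probes were higher in RBSDV and 3519 were lower (adjusted p under 0.05). At least 2-fold differences made up 438 of the higher and 2440 of the lower probes. The 4 RBSDV values lay entirely above or below the 4 mock values at 27.7% of tested probes, where chance gives 2.86% for 4 independent arrays against 4. The share was 37.2% with mock pairs averaged (chance 13.3% for 4 against 2) and 48.2% with the arrays of a slide averaged in both groups (chance 33.3% for 2 against 2). These chance shares assume no shift common to many probes, while the median difference over tested probes was -0.22. Probes are also not independent of each other. An excess over these shares therefore cannot be tied to the infection. With the mock arrays of each slide averaged, 10 probes were higher and 167 lower, each at least 2-fold. Of these 177, 164 had also been called with 8 arrays, a fit to the same data. The same averaged samples gave 11 higher and 19 lower after quantile normalization, and 83 higher and 548 lower with slide as a block. The median size of the 177 differences was 2.71 on the log2 scale. Mostly large differences could pass, as in simulation this fit recovered 4 of 50 probes changed by a log2 fold of 1. With the arrays of a slide averaged in both groups, limma called 0 probes, with 3774 at an unadjusted p under 0.05, and with these pairs as a random block it called 3.

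The second count is given because the 4 mock arrays formed 2 pairs of near-duplicates. Over bright probes, mock replicates 1 and 4 differed by a robust SD of 0.13 on the log2 scale, 1.06 times the noise of repeated control spots, and mock replicates 2 and 3 by 0.15, 1.23 times that noise. The mock arrays of a pair therefore differed by about spot noise and were counted as 1 sample in each mean ± SD. The labels call them separate samples. RBSDV replicates of one slide differed by 0.25 and 0.21, 1.88 and 2.63 times spot noise, against 0.34 to 0.42 between slides. They too grouped by slide but were counted as 4 samples. The p-values with mock pairs averaged, and the RBSDV SDs with n = 4, may therefore still be too small. Averaging only the mock pairs rests on the spread over bright probes. Over all tested probes Pearson's r within a slide was nearly alike, at 0.991 and 0.9901 in mock and 0.9885 and 0.989 in RBSDV. Simulations without a group effect gave arrays of a slide and group shared deviations, of equal spread in mock and RBSDV, unlike the data. There the fit to 8 arrays still called a median of 1322 probes, against 17 with mock pairs averaged. The latter fit made 144 false calls in a simulation with 50 probes changed at each of 4 sizes, in which RBSDV arrays of a slide shared deviations too.

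**Figure D1:**
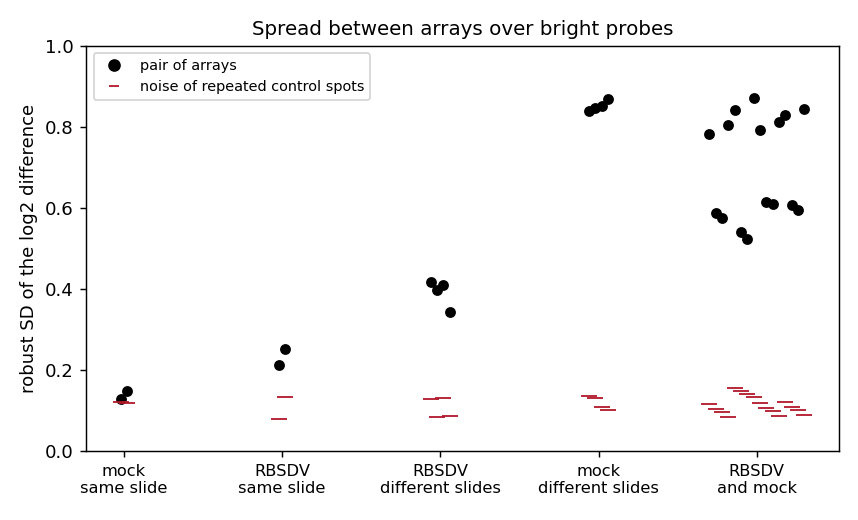
Robust SD of the log2 difference between each pair of arrays over 14323 bright probes (black points), by kind of pair, with the noise of repeated control spots on the same arrays (red dashes). Mock arrays of one slide lie at 0.13 and 0.15, near the noise, while mock arrays of different slides lie between 0.84 and 0.87.

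The fixed ranking by fitted difference put TC296602 first among the increases, a consensus contig whose gene the files do not name. Its log2 level relative to the array's 75th percentile was 0.24 ± 0.98 (SD, n = 4) in RBSDV and -6.38 ± 2.68 (SD, n = 2) in mock. The difference was 6.62 (SE 1.04, limma adjusted p = 0.0128 with 8 arrays and 0.059 with mock pairs averaged), and the probe was well above background on 2 of the 4 mock arrays, so its size rests partly on unmeasured levels. Under normexp correction it was 4.00, below the 5.41 of TC286791. After percentile scaling, TC286791 followed with a difference of 5.95 (SE 1.53, adjusted p = 0.043 and 0.154), and its RBSDV level was split by slide, with means of 0.00 on slide 1 and 6.11 on slide 2. With slide as a block and mock pairs averaged, TC296602 passed the threshold (adjusted p = 0.0474) and TC286791 did not (0.0803). That fit assumes the same slide shift in both groups.

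TC315780 came first among the decreases by fitted difference, but its size is only a bound, and TC315411 came before it under normexp correction (-4.15 against -3.17), quantile normalization (-5.59 against -5.42) and in the deposited value table. It was not well above background on any RBSDV array and was at least 41.5-fold lower there than in mock (adjusted p = 0.0287 with 8 arrays and 0.0789 with mock pairs averaged). Its mock level differed between slides, at 1.27 on slide 1 and -4.49 on slide 2. TC315411, measured on all 8 arrays, was 66.9-fold lower in RBSDV after percentile scaling, with log2 differences of -6.73 on slide 1 and -5.39 on slide 2. Its level was -5.96 ± 0.70 (SD, n = 4) in RBSDV and 0.10 ± 0.95 (SD, n = 2) in mock, a difference of -6.06 (SE 0.47, adjusted p = 0.00243 with 8 arrays and 0.0379 with mock pairs averaged). Of the 4 sequences, only TC315411 passed the threshold in both fits, and it did not pass with the arrays of a slide averaged in both groups (adjusted p = 0.387) or as a random block (0.177). The direction of all 4 was the same under each of the 6 scalings. They were ranked by size, and the scalings moved the median of all probes only between -0.26 and 0.29, so a reversal was unlikely.

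**Figure D2:**
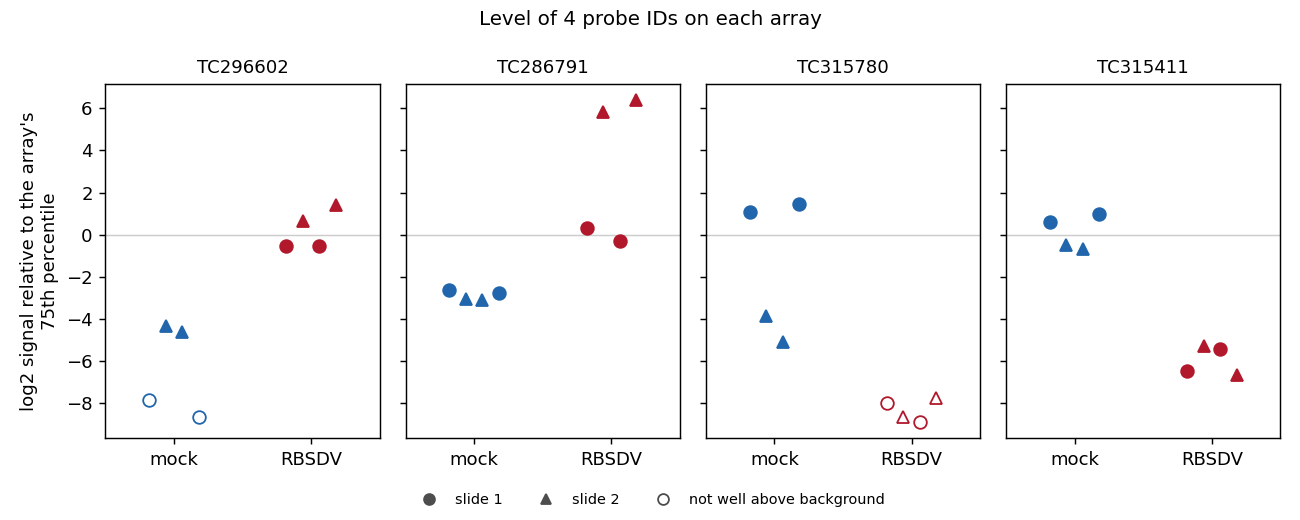
Log2 signal relative to the array's 75th percentile for 4 probe IDs on each mock (blue) and RBSDV (red) array, circles for slide 1 and triangles for slide 2, open where not well above background. The ranking rule required the 4 RBSDV values to lie on one side of the 4 mock values. The RBSDV values of TC286791 fall into a pair near 0 and a pair near 6 by slide.

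The balance of higher and lower probes depended on the scaling. Lower probes made up 77.2% of the calls after percentile scaling and 47.3% after quantile normalization, with 1668 higher and 1499 lower. Scaling to the bright E1A control probes, an alternative added after the data were seen, gave 14.8%, with 4670 higher and 811 lower. The median difference over all tested probes was -0.22 on the log2 scale after percentile scaling, 0.05 after quantile normalization and 0.29 after scaling to the controls. The E1A controls lay 3.44 to 3.59 above the 75th percentile on RBSDV arrays and 3.78 to 4.25 above it on mock arrays. Normexp correction gave 1999 higher and 9743 lower probes.

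The difference between infected and mock plants was also taken on each slide, which held 2 arrays of each group. Because the mock arrays of a slide differed by about spot noise, the fits within a slide compare RBSDV with what amounts to 1 mock sample, and their p-values are too small. Within slide 1, 7374 probes were higher and 9869 lower in RBSDV, and within slide 2, 1540 were higher and 4582 lower. The lists shared 623 higher and 1945 lower probes, where independent lists of these sizes would share 316 and 1257. Another 585 probes were higher on slide 1 and lower on slide 2, and 293 the opposite. The test of the difference itself called 11919 probes (33.1% of those tested) as differing between slides, among them 882 of the 4559 called over 8 arrays. This test sets the mock slides apart against near-technical spread. With each mock pair counted as 1 sample, assumed to vary like RBSDV arrays of a slide, it called 5620. Across probes, which are not independent replicates, the differences of both slides correlated with Pearson's r of 0.288, and 61.6% had the same sign. With slide as a block, 2367 probes were higher and 6661 lower. A block assumes a slide shift common to both groups. The slope over probes of the RBSDV slide difference on the mock slide difference was only 0.0946, so this assumption did not hold across probes.

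**Figure D3:**
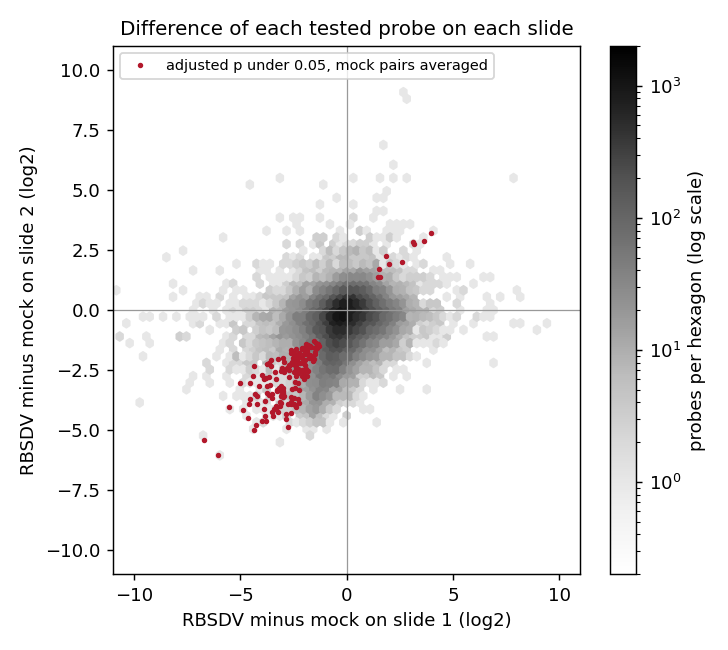
RBSDV minus mock difference (log2) of each tested probe on slide 1 (horizontal) and slide 2 (vertical), in hexagons shaded by the number of probes on a log scale. Red points are the 177 probes past the threshold with mock pairs averaged, 10 in the upper right and 167 in the lower left, and 61.6% of all probes have the same sign on both slides.

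Without RBSDV replicate 1, 298 probes were called higher and 928 lower, without RBSDV replicate 2, 434 and 1415, without RBSDV replicate 3, 218 and 782, and without RBSDV replicate 4, 185 and 686. Without mock replicate 1 the counts were 461 and 2025, without mock replicate 2 they were 990 and 3058, without mock replicate 3 they were 729 and 2703, and without mock replicate 4 they were 504 and 2443.

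Probes of the Mutator transposon family were lower in value in infected plants after percentile scaling, without passing the planned test singly. MuDR is the autonomous Mutator element of maize, and its mudrA gene encodes the transposase. The 4 MuDR probes had differences from -0.59 to -0.09, with a median of -0.47, which is -0.25 relative to the median of all probes. MUDRB was at -1.58 ± 0.11 (SD, n = 4) in RBSDV and -0.99 ± 0.32 (SD, n = 2) in mock (limma adjusted p = 0.0641 with 8 arrays and 0.157 with mock pairs averaged). With slide as a block it passed with 8 arrays (0.0322) and not with mock pairs averaged (0.123). Under normexp correction MUDRB also passed with 8 arrays (0.0316). MUDRA-21 differed by -0.49 (SE 0.16, adjusted p = 0.0743), MUDRA by -0.45 (SE 0.21, adjusted p = 0.168) and MUDR-TIRA by -0.09 (SE 0.23, adjusted p = 0.793). With mock pairs averaged the limma adjusted p of these was 0.181, 0.289 and 0.836. As a set the 4 probes were shifted downwards by limma's fry (adjusted p = 0.00264 with 8 arrays and 0.0072 with mock pairs averaged, over the 2 sets tested), which does not compare them with other genes. Limma's camera, which does, gave an adjusted p of 0.34 and 0.414. All 4 were lower in value under percentile, normexp, quantile and median scaling and in the deposited value table, but 3 of the 4 were higher under scaling to the E1A controls. That scaling raised the median of all probes to 0.29, and the MuDR median of 0.04 stayed below it. Under quantile normalization the MuDR median was -0.39 against 0.05 over all probes. The MuDR median lay below that of all probes under each of the 6 scalings. On slide 1, 3 of the 4 were lower in value, and on slide 2 all 4 were.

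Genes of sister chromatid cohesion showed no called difference in the planned fit. RAD21, SMC1 and SMC3 are cohesin subunits, and shugoshin (SGO1) protects cohesin at centromeres. Of the 14 tested probes for ZmRAD21, ZmSMC1, ZmSMC3 and ZmSGO1, 11 were lower in value and 3 higher after percentile scaling. Their differences ran from -0.88 to 0.20 with a median of -0.18, which lies 0.04 above the median of all probes. The 7 ZmRAD21 probes were dim, with mean levels from -6.25 to -3.84 in RBSDV, where the median of tested probes was -2.10 to -2.06. After percentile scaling 97.7% of calls in the dimmest of 3 equal classes of probes were lower. All 7 ZmRAD21 probes had values below 0, from -0.88 to -0.04, and the lowest adjusted p among them was 0.0585. With slide as a block that probe passed with 8 arrays (adjusted p = 0.0323) and not with mock pairs averaged (0.108). Under normexp correction 2 ZmRAD21 probes passed with 8 arrays (limma adjusted p = 0.0212 and 0.0371). Under quantile normalization 4 of the 7 ZmRAD21 probes were higher in value, and under scaling to the E1A controls also 4, of which 3 were shared. The median of the 7 was 0.26 and 0.08, against 0.05 and 0.29 over all probes. The 2 ZmSMC1 probes had differences of 0.08 and 0.20, the 4 ZmSMC3 probes from -0.29 to -0.06, and ZmSGO1 had 0.07. Under scaling to the E1A controls all 7 of these were higher in value, from 0.22 to 0.71, where the median of all probes was 0.29. Both ZmSMC1 probes then passed (limma adjusted p = 0.0376 and 0.0203). Quantile normalization put 5 of the 7 higher in value. For the 14 probes after percentile scaling, limma's fry gave an adjusted p of 0.0852 with 8 arrays and 0.0468 with mock pairs averaged. Camera, which compares them with other genes, gave 0.784 and 0.738. AM1, a gene required for entry into meiosis, differed by -0.49 at the 1 tested probe of 3. Its SE was 0.22 (limma adjusted p = 0.156 with 8 arrays and 0.267 with mock pairs averaged). The AM1 probe passed with 8 arrays under normexp correction (0.031), where 9743 probes were called lower, and with array weights (0.0254). The probe matched to LOC100279569 differed by -0.13 (SE 0.24, adjusted p = 0.722).

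In the planned fit limma called 0 of the 20 named probes at an adjusted p under 0.05. This held over all tested probes and adjusted over the named probes alone (lowest 0.0973), and 4 had an unadjusted p under 0.05.

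**Figure D4:**
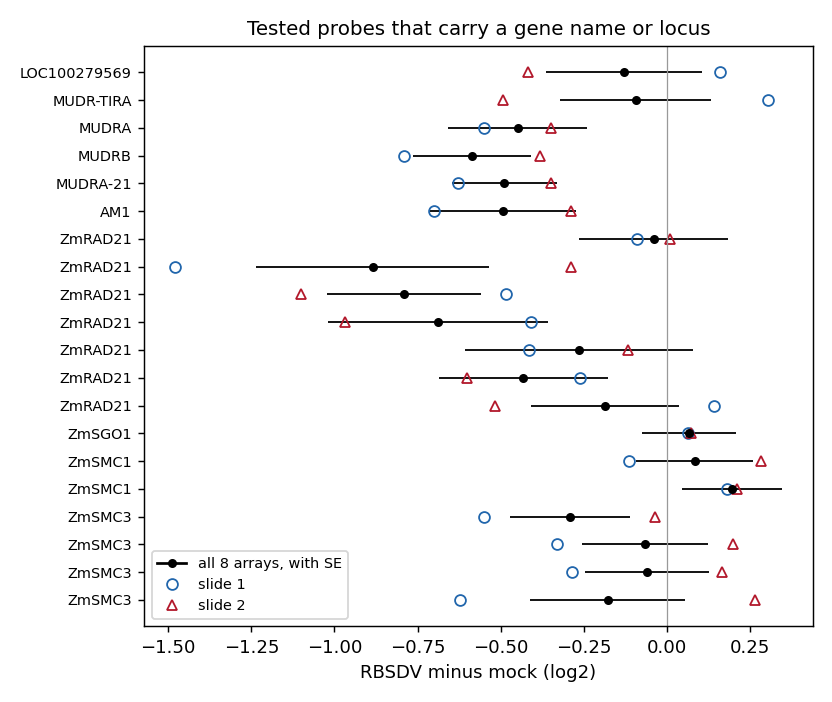
RBSDV minus mock difference (log2) of the 20 tested probes that carry a gene name or matched a locus, over 8 arrays with the SE (black), on slide 1 (blue circles) and on slide 2 (red triangles). The 4 MuDR probes lie between -0.59 and -0.09 and the 7 ZmRAD21 probes between -0.88 and -0.04 over 8 arrays after percentile scaling, and 4 ZmRAD21 probes turn positive after quantile normalization.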

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

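Of the tests in this part, the slope between slides, the comparison of probes sharing an ID and the test of slide differences with mock pairs counted once were chosen only after the results they measure were seen.

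The RBSDV minus mock difference differed between slides at 11919 probes (limma, test of the difference of differences). That test takes its mock spread from pairs of arrays at 1.06 and 1.23 times spot noise, so it compares what amounts to 1 mock sample per slide. With each mock pair counted once and assumed to vary like RBSDV arrays of a slide, 5620 probes were called. The mock arrays differed more between slides than the RBSDV arrays did: 331 probes were at least 8-fold higher on slide 1 and 581 at least 8-fold lower in mock, against 66 and 75 in RBSDV. A slide or hybridisation batch shared by both groups would move RBSDV arrays alike. The slope over probes of the RBSDV slide difference on the mock slide difference was only 0.0946. It cannot speak to a batch of the mock arrays alone, such as separate labelling. The negative controls were raised on the slide 2 mock arrays, with net signals of 29.9 and 17.4 against 12.8 to 14.7 on the other arrays. Raised signal of dim probes alone would leave bright probes alike, yet in the brightest of 3 equal classes of probes the SD of the mock slide difference was 2.13 times that of RBSDV. A sequence difference under single probes stays open: of probes 8-fold apart between mock slides that had 1 partner probe of the same ID, 94.1% had a partner moving the same way (80 of 85), but the files do not place the probes, so partners could overlap. A difference in the plants, such as their growth conditions or a sample from other material, may also remain and was not tested.

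Among the 4 ranked sequences, the difference on slide 1 minus that on slide 2 was -5.99 for TC315780, 2.19 for TC296602 and -6.51 for TC286791, each past the threshold of the same test over 8 arrays. With mock pairs counted once the adjusted p was 0.0253, 0.0555 and 0.0209, so TC296602 did not pass. These sizes rest partly on unmeasured levels, as TC315780 was not well above background on any RBSDV array and TC296602 on neither mock array of slide 1. The value was -1.19 at one ZmRAD21 probe, and -0.528 and -0.886 at a pair of ZmSMC3 probes, none of which passed with mock pairs counted once (adjusted p 0.0922, 0.189 and 0.0784).

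Of 56 groups of 4 arrays checked for a value far from the rest, 3 held one, where chance gives about 1 in 20. RBSDV replicate 3 was low at MUDRA-21 (log2 level -2.39). RBSDV replicate 4 was low at a ZmRAD21 probe (-6.91), and mock replicate 2 was high at another ZmRAD21 probe (-3.58).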

How the results depend on the processing

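The averaged and randomly blocked pairs, the combinations with them, scaling to controls, value-table numbering and the choice of mock slide were added after the data were seen, and so were the counts over splits. Counts are given as higher, lower, at least 2-fold higher and at least 2-fold lower, against 1040, 3519, 438 and 2440. All 4 stayed within 1.5 times under median scaling, for probes well above background on all 8 arrays, and with an intensity trend and robust spread. Where counts moved, the cause was not tested unless stated.

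Normexp correction gave 1999 higher, 9743 lower and 1380 at least 2-fold lower. Quantile normalization gave 1668, 1499, 863 and 989, and values deposited by the authors gave 1674, 1504, 862 and 989. Without the filter on dim probes 691 were higher. Array weights, which ranged from 0.134 to 4.25, gave 7867, 12097, 3436 and 4736. Slide as a block gave 2367, 6661, 764 and 3878. Within slide 1 there were 7374, 9869, 3717 and 4672, and within slide 2 there were 916 and 3747 at least 2-fold. The stricter threshold of 0.01 by construction left 84, 319, 80 and 315. Leaving out each array gave 185 to 990 higher, 686 to 3058 lower, 139 to 548 at least 2-fold higher and 638 to 2162 at least 2-fold lower, with fewer samples in each.

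With mock pairs averaged, 10 and 167 were called, all at least 2-fold (10 and 167). With all pairs averaged, 2 samples against 2, limma called 0 in either direction and at either size, with 3774 probes at an unadjusted p under 0.05. The pair as a random block (correlation 0.762) gave 1, 2, 1 and 2, with 4302 at an unadjusted p under 0.05. Mock pairs averaged gave 11 and 19 after quantile normalization and 83 and 548 with slide as a block, all at least 2-fold. Scaling to E1A controls gave 4670, 811, 2144 and 670. Against mock arrays of slide 1 alone there were 6204, 8573, 3417 and 4169, and of slide 2 alone 2139, 8737, 723 and 6191.

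The replicate block gave 187, 1391, 183 and 1378. Deviations of same-numbered samples correlated across probes at 0.07, 0.26, -0.23 and 0.01, and 2 of the 8 samples were closest to their own number. With the value table's numbers for mock replicates 3 and 4, the correlations were 0.07, 0.26, 0.21 and 0.07 and the block gave 473 and 1991. By the value table's numbers every same-numbered pair lies on one slide, while by the scanner numbers the pairs numbered 3 and 4 do not. The change in their correlations may therefore reflect a shared slide. Neither numbering has every correlation above 0.1, so no pairing was taken from it.

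Of the 4 ranked sequences, TC315411 kept its direction and call in 28 of 30 alternatives, TC296602 in 24 of 29, TC315780 in 14 of 29 and TC286791 in 11 of 30. None changed sign. Their adjusted p ranged up to 0.387, 0.472, 0.472 and 0.474, in that order. Most of these alternatives counted the mock arrays of a pair as separate samples. With mock pairs averaged only TC315411 passed (limma adjusted p = 0.0379), and TC296602 did so only with slide as a block added (0.0474). TC315780 and TC286791 passed in no fit with averaged or randomly blocked pairs. Probes with gene names passed the threshold in 32 cases, each 1 probe under 1 alternative, and stayed below it in 567.

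Of 35 splits of the 8 arrays into equal groups, 1, the real one, called as many as 4559 probes, and the highest other, the split by slide, called 664. These splits do not exclude chance: 32 of them part a pair of similar arrays, which widens the spread within their groups, and 3 keep the pairs, too few for a share under 0.05. With mock pairs averaged, 15 splits of 6 samples are too few for a share under 0.05: the real split called 177 (1 split as large) and the highest other 4. Camera with an estimated correlation, fry and the mean of all probes per gene were not run for the gene lists, because no list could be matched to probes. Signal over background limits dim probes: 6050 were not tested.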

Other observations

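Of the tests in this part, the share of lower calls by brightness, the ratio of pair spread to spot noise, the simulation without a group effect and the averaging of mock pairs were chosen after the results they measure were seen.

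Detection differed between the groups. Of all probes, 213 were well above background on the 4 mock arrays and on 0 RBSDV arrays, and 11 showed the opposite. Another 2004 were well above background only on the mock arrays of slide 2, against 22 only on the mock arrays of slide 1. The net signal of the negative controls was 29.9 and 17.4 on the slide 2 mock arrays and 12.8 to 14.7 on the other arrays. Consensus contigs made up 892 of the higher and 2085 of the lower calls over 8 arrays (24748 tested), and single sequence accessions 148 and 1406 (10953 tested). The median signal of these classes was 535 and 81.1, and after quantile normalization their calls were 1319 higher and 1004 lower, and 345 and 489. Of 1855 IDs with several tested probes, 85 had at least 2 called and 3 had probes called in both directions.

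The excess of lower over higher calls lay mostly among dim probes. With tested probes in 3 equal classes by mean signal, 97.7% of calls were lower in the dimmest class and 58.4% in the brightest. After quantile normalization these shares were 51.3% and 43.6%. A candidate explanation is that one factor per array does not bring the dim ends of the arrays together, which the values are in line with. A real excess of lower dim transcripts in infected plants was not tested separately and stays open.

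The number of calls fell from 4559 to 177 when each mock pair was averaged. A candidate explanation is that the mock arrays of a slide are repeat hybridisations of 1 RNA. The larger of the ratios of pair spread to spot noise was 1.228, between the value of 1 that repeated spots would give and the 1.5 set as a bound against it, so repeats and closely matched pools cannot be told apart. Shared deviations within pairs may raise the count over 8 arrays. With no group effect and spreads pooled over both groups, they gave a median of 1322 simulated calls. This is below the real 4559 but not small against it. How many of the 4559 reflect the infection stays open.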
